A study of Mus musculus with 10 samples.

How the data were processed

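Total RNA was extracted from mouse embryonic stem cells grown on gelatin-coated plates, per the labels' protocols, and sequenced as 10 libraries in 5 groups of 2. Group and replicate were taken from the labels, whose titles carry 2 series of names, LEM and MLE, of unstated meaning, with 1 library of each group in each series. The authors deposited whole-number read counts per gene, which are not normalized. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.4, HTSeq 0.5.4p5 and DESeq2 (version not given) were used with mouse genome build mm9. The annotation, the strand setting of the counting and the read layout are not given in the sources used here. Genes are named by the symbols in the files. Because the reference at hand was of another build, no coordinates are printed.

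Each deposited count table held 24015 genes and 5 summary categories, which were kept out of library sizes and tests. Records outside features made up 10.34 to 11.78% of all records, ambiguous records 0.69 to 0.73% and records of reads aligned to more than 1 place 33.41 to 36.51%, and gene counts made up 51.16 to 54.81%. Since such reads were not counted for any gene, genes with near-identical copies are under-counted, and values for ribosomal proteins, Zscan4, Xlr5 and other multicopy genes are uncertain. Without a known strand setting, overlapping and antisense genes are uncertain too. Gene counts totalled 21162844 and 19422934 in serum (replicates 1 and 2), 21261219 and 20397075 in first 2i, and 16809070 and 18780882 in long 2i. They totalled 27766338 and 21589691 in serum return and 18412529 and 19017245 in second 2i.

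Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by group (minimum count 10, minimum total 15), which left 14220. TMM factors were used, and a quasi-likelihood model with robust estimation was fitted to all 10 libraries with the group as the only term, leaving 5 residual degrees of freedom. The groups thus shared 1 estimate of the spread (common biological coefficient of variation 0.049). There were 8 contrasts: first 2i against serum, long against first 2i, long 2i against serum, serum return against long 2i, serum return against serum, second 2i against serum return, second against first 2i, and the difference between the second and the first response to 2i. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene counted as changed at an adjusted p under 0.05. Contrasts against the same libraries share their chance values, and no overlap between such contrasts is tested. Statements that join them, such as genes that fell in first 2i and rose again in long 2i, carry this limit. Standard errors of log2 fold changes were derived from the fold change and the F statistic.

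Levels are CPM, the gene's count scaled to the library's total over the genes that passed the filter, multiplied by its TMM factor, given as mean ± SD. Folds come from the model. Where a group held no counts of a gene, the fold is a bound against 3 counts over the group, and where it held 1 to 3 counts no fold is given, except fitted values that are said to depend on the prior count. Principal components were computed on log2 CPM with a prior count of 2.

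Gene lists numbered 25 and were written from textbook knowledge of stem cells, Wnt and ERK signalling, imprinting, DNA methylation, lineage and other-cell markers, metabolism and housekeeping complexes. Some genes stand in 2 lists, such as Dnmt3a, Dnmt3b, Myc and Phlda2. Each list was tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg adjustment over the lists of a comparison, lists with at least 5 tested members). Alternatives were camera with a correlation estimated for each list, fry, and counts of changed members adjusted over the list alone, of which the text gives the direction that differs. Of the 87 calls over all comparisons 18 held with an estimated correlation.

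Per comparison the text names genes by a rule. It took the 5 genes higher and the 5 lower with the largest fold change among genes that passed, had a mean of at least 5 CPM in the higher group and moved the same way in all 4 library pairs, leaving out symbols that are only model names and ribosomal protein or histone genes. It also took up to 4 members of a list that passed, and always Pou5f1, Sox2, Nanog, Esrrb, Axin2, Dnmt3a, Dnmt3b, Dnmt3l, H19 and Meg3. The text names part of these, some are not reported here, and genes outside the rule are said to have been chosen after their values were seen. The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

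Alternatives were DESeq2's size factors in edgeR (RLE), no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the title series as a block, and leaving out each library in turn, where the lone library of a group was assumed to vary like the others. Leaving out the gene Rn45s was added after the data had been seen, because its level differed most between the libraries of serum return. The code was tested on simulated counts for first 2i against serum (13497 genes, 100 changed by each of 2 fold sizes). edgeR recovered 96 of 100 genes changed 1.5-fold and 99 of 100 changed 2-fold with 14 false calls, and DESeq2 recovered 87 and 100 with 9 false calls. The changed genes all had a mean of at least 5 CPM in serum and were far fewer than the 70% called in the data. The simulation thus checks the code and does not test scaling or false calls where most genes change.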

Results

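The series measured gene expression in mouse embryonic stem cells that carry a reporter of Wnt/β-catenin signalling, grown either in serum with leukaemia inhibitory factor (LIF) or in 2i with LIF. 2i is a pair of kinase inhibitors, here 3 µM of a GSK3 inhibitor and 1 µM of an ERK pathway inhibitor, and the cells were split every 48 h. The 10 RNA-seq libraries fall into 5 groups of 2: original serum culture, 2i for 5 to 6 passages (first 2i), 2i for more than 13 passages (long 2i), long 2i followed by 6 passages in serum (serum return), and 2i followed by 6 passages in serum and 4 to 5 further passages in 2i (second 2i). The label of second 2i gives its earlier 2i culture as 13 passages, not more than 13. That label does not say that second 2i was grown from the serum return sampled here. Counts assigned to genes totalled 16809070 to 27766338 per library, and levels are given as CPM (counts scaled to the library's total over tested genes, adjusted by its TMM factor). The floor used for a gene with no counts in a group was 3 counts over the 2 libraries of the group, which corresponded to 0.0608 to 0.0837 CPM. All values are means ± SD over n = 2 libraries per group. Floors cover counting error only. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

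Medium was the main axis of variation. The first principal component of log2 CPM held 65.8% of the variance and placed all 4 serum libraries at scores of -84.2 to -77.3 and all 6 libraries from 2i at 43.3 to 63.8. On the second component, with 18.7% of the variance, the long 2i libraries scored -62.1 and -61, whereas first 2i scored 38.2 and 39.6 and second 2i 28.7 and 29.1. The replicates of serum return differed in Rn45s, the ribosomal RNA precursor, at 2496 and 15480 CPM. Without the 50 genes that differed most, their chi-square per degree of freedom was 3.6, against 2.9 to 4.07 in the other groups. No replicate pair was as close as sampling noise alone, and each library was counted as a sample.

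**Figure D1:**
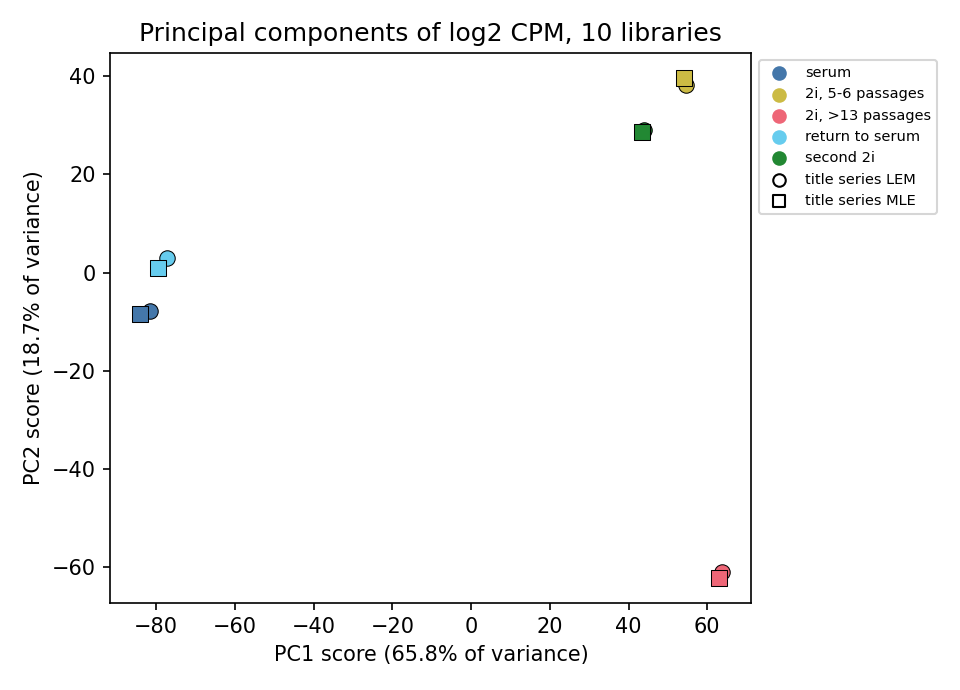
Scores of the 10 libraries on the first (x axis, 65.8% of variance) and second (y axis, 18.7%) principal components of log2 CPM, coloured by culture, with the marker shape giving the title series. The serum libraries lie at the left and the 2i libraries at the right, where long 2i stands apart on the second component.

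How cells from serum changed over their first 5 to 6 passages in 2i was tested first. Axin2, a feedback inhibitor of the Wnt pathway that inhibition of GSK3 is known to activate, rose 25.7-fold from 2.68 ± 0.48 to 68.7 ± 2.6 CPM. Sp5, a transcription factor induced by β-catenin, rose 138-fold from 0.0999 ± 0.0061 to 14.6 ± 3.7 CPM. Spry4, a feedback inhibitor of the ERK pathway, fell 236-fold from 407 ± 1.3 to 1.71 ± 0.29 CPM, and the transcription factors Etv4 and Egr1 fell 61.2-fold and 63.3-fold. Dnmt3l, the cofactor of the de novo DNA methyltransferases, fell 88-fold from 370 ± 1.3 to 4.19 ± 0.35 CPM.

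In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 9952 of 14220 genes changed (70%), 4996 higher and 4956 lower, and 3645 changed by at least 2-fold. The pluripotency factors kept high levels. Nanog rose from 719.7 ± 14 to 1118 ± 1.8 CPM and Esrrb from 1016 ± 45 to 1143 ± 35 CPM. Pou5f1 fell from 1213 ± 19 to 1064 ± 16 CPM, and Sox2 did not pass (793 ± 25 against 815 ± 1.2 CPM, edgeR adjusted p = 0.447). The edgeR call for Esrrb was lost without replicate 1 of serum (adjusted p = 0.0725) or replicate 2 of first 2i (adjusted p = 0.0568). Among the largest increases of genes with a mean of at least 5 CPM in either group, the homeobox gene Nkx1-2 was at least 179-fold higher (13.4 ± 0.85 CPM) and Gad2, an enzyme of GABA synthesis, at least 91.6-fold higher (6.85 ± 0.3 CPM). Cyp1a1, a cytochrome P450 of xenobiotic metabolism, was at least 89.5-fold higher (6.7 ± 0.65 CPM). These bounds were set against a floor of 3 counts over the 2 serum libraries, which held none. Car8, a carbonic anhydrase-related protein, rose 167-fold to 46.8 ± 1.1 CPM. The largest decreases at that level were those of Robo4, a receptor known from endothelium, from 55.1 ± 5 to 0.0964 ± 0.07 CPM, AU015836, from 53.1 ± 2.6 to 0.143 ± 0.0041 CPM, and Spry4. They were followed by Myrf, the myelin regulatory factor, from 118 ± 12 to 0.648 ± 0.25 CPM and the homeobox gene Prrx2, from 20.3 ± 4 to 0.12 ± 0.037 CPM. Pof1b, an actin-binding protein, read 6.12 ± 0.65 CPM in 2i and 1 count in serum.

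Among the lists fixed before the data were examined, 18 of 19 ERK pathway targets fell and 1 did not pass (median log2 fold change -2.12; camera adjusted p = 4.46e-28, and adjusted p = 0.0116 with an estimated correlation). Myc fell 20.1-fold to 4.66 ± 0.37 CPM. Of 21 glycolysis genes 17 fell and 4 rose (camera adjusted p = 1.15e-10), with Slc16a3, a lactate transporter, down 26.8-fold, Pfkl, a phosphofructokinase, 6.65-fold and Slc2a1, a glucose transporter, 6.17-fold. That call had adjusted p = 0.126 with an estimated correlation. In cholesterol synthesis 19 of 24 genes rose and 3 fell (camera adjusted p = 0.00545, and adjusted p = 0.126 with an estimated correlation), among them Msmo1 from 115 ± 4.5 to 239.6 ± 4.6 CPM. Formative and primed epiblast genes went both ways, 4 up and 10 down of 17 (median -0.76; camera adjusted p = 0.000393, and adjusted p = 0.13 with an estimated correlation). Pou3f1, an epiblast transcription factor, fell from 4.67 ± 1.7 to 0.0721 ± 0.036 CPM, whereas the zinc finger gene Zic2 rose from 1.45 ± 0.23 to 20 ± 0.34 CPM. Of 29 genes of DNA methylation and retroelement repression 13 fell and 10 rose (camera adjusted p = 0.0403, and adjusted p = 0.146 with an estimated correlation). The methyltransferase Dnmt3b fell 5.11-fold to 28.6 ± 2.1 CPM and Dnmt3a 2.16-fold to 23.6 ± 1.3 CPM, and Dppa3, which protects maternal methylation in the zygote, rose from 0.913 ± 0.33 to 12.6 ± 0.53 CPM.

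Of 20 p53 targets and cell-cycle inhibitors 13 rose and 5 fell (camera adjusted p = 0.0139, and adjusted p = 0.205 with an estimated correlation). This list, shortened to p53 targets elsewhere, mixes p53 targets with cell-cycle inhibitors such as Cdkn2a and does not measure p53 activity alone. Cdkn1a rose 11.7-fold to 219 ± 0.77 CPM and Cdkn2a from 0.576 ± 0.07 to 29.8 ± 3.1 CPM, while Pmaip1, a pro-apoptotic BH3 protein, fell 8.88-fold. Endoderm markers fell in 10 and rose in 4 of 19 (camera adjusted p = 0.00545, and adjusted p = 0.146 with an estimated correlation), led by Col4a1, a basement membrane collagen, from 127 ± 13 to 0.835 ± 0.01 CPM. Markers of fibroblasts and feeder cells (1 up, 7 down of 11) and of blood and endothelium (1 up, 3 down of 10) were not called (camera adjusted p = 0.0514 and 0.456). Thy1 fell from 13.7 ± 1.6 to 0.452 ± 0.088 CPM and the endothelial cadherin Cdh5 from 6.03 ± 0.54 to 0.117 ± 0.17 CPM.

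The remaining lists were not called by camera. Among pluripotency genes 9 rose and 15 fell of 28 (adjusted p = 0.233), with the homeobox gene Gbx2 down 29.2-fold and Lin28a, a repressor of let-7 microRNAs, down 6.36-fold. Of 22 Wnt/β-catenin targets 10 rose and 6 fell (adjusted p = 0.444). Of 28 pathway components 9 rose and 11 fell (adjusted p = 0.666; median -0.02, mean 0.11), including Wls, needed for Wnt secretion, up to 35.4 ± 1.1 CPM. TGF-β and BMP targets counted 3 up and 6 down of 13 (adjusted p = 0.0514), with the BMP target Id1 down 68.8-fold to 2.69 ± 0.16 CPM and the Nodal antagonist Lefty2 up to 868 ± 12 CPM. 9 of 17 Hox genes rose and 1 fell (adjusted p = 0.0514; median 3.8, or 1.55 with genes lacking counts in a group at their bound), with Hoxc13 at 11 ± 0.011 against 0.0999 ± 0.0061 CPM. Y-linked genes rose in 6 of 6 (adjusted p = 0.0514), and the histone demethylase Kdm5d read 2.68 ± 0.35 CPM against 1 count in serum.

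Maternally expressed imprinted genes numbered 3 up and 14 down of 23 (adjusted p = 0.0941), and paternally expressed ones 11 up and 11 down of 26 (adjusted p = 0.853). Plagl1, a zinc finger transcription factor, rose 14.2-fold to 260.1 ± 7 CPM, Dio3, a thyroid hormone deiodinase, from 0.15 ± 0.0091 to 12.9 ± 1.8 CPM and Meg3 from 134 ± 8.5 to 159 ± 5.1 CPM. H19 read 4.69 ± 0.67 CPM in serum and 1 count in 2i. Germline genes counted 14 up and 7 down of 32 (adjusted p = 0.323) and 2-cell-like genes 1 up and 16 not passing of 17 (adjusted p = 0.853; median 0.47, 0.28 with bounds). Trophectoderm genes had 6 up and 6 down of 16 (adjusted p = 0.666; median -0.08, mean 0.07), and primitive streak and mesoderm genes 5 up and 4 down of 13 (adjusted p = 0.444). The transcription factor Tfap2a rose 23.4-fold to 59.2 ± 0.64 CPM. Neuroectoderm genes, 4 up and 6 down of 10 (adjusted p = 0.666), had a median of -0.43 although camera ranked them upward, and included the neurofilament gene Nefl, which rose 28.3-fold to 39.7 ± 0.15 CPM. SRF and YAP targets split 8 up and 8 down of 18 (adjusted p = 0.949; median -0.21, camera upward). Ribosomal protein genes counted 14 up and 32 down of 79 (adjusted p = 0.456), and oxidative phosphorylation genes 22 up and 36 down of 79 (adjusted p = 0.444). Ribosomal protein genes share reads with pseudogenes and are uncertain. Counts adjusted over the list alone were the same for every list except ribosomal proteins (14 up, 29 down) and 2-cell-like genes (17 not passing).

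Long 2i was compared with first 2i to find what changed with time in the same medium. The Nodal antagonists Lefty1 and Lefty2 both fell, Lefty1 189.8-fold from 139 ± 1.1 to 0.734 ± 0.22 CPM and Lefty2 82.7-fold from 868 ± 12 to 10.5 ± 0.68 CPM. The neurofilament genes Nefm and Nefl rose 31.2-fold and 3.49-fold, to 127 ± 5.8 and 138 ± 2.5 CPM. Several genes that had fallen in first 2i rose again: Dnmt3l rose 19.9-fold to 83.6 ± 0.85 CPM, Dnmt3b 6.24-fold to 179 ± 7.1 CPM and the ERK targets Spry4 and Etv4 11.4-fold and 30-fold, to 19.7 ± 0.9 and 138 ± 4.2 CPM. Axin2 did not differ beyond the spread (74.1 ± 1.5 against 68.7 ± 2.6 CPM, edgeR adjusted p = 0.162).

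The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 8699 genes (61.2%), 4324 higher and 4375 lower, 2400 of them by at least 2-fold. Sox2 fell 2.02-fold, from 793 ± 25 to 393 ± 15 CPM, Nanog from 1118 ± 1.8 to 887 ± 29 CPM, Esrrb 1.17-fold and Pou5f1 1.16-fold, and Dnmt3a fell 1.36-fold while Meg3 rose 1.99-fold. Efhc2 and Rcsd1 were also among the largest increases of genes with at least 5 CPM in either group, at 74.1 ± 0.082 and 5.32 ± 0.5 CPM from 1.48 ± 0.38 and 0.141 ± 0.13 CPM. Krt7, a keratin of simple epithelia, fell 59-fold to 0.141 ± 0.051 CPM. H19 stayed at or below 3 counts in both groups.

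ERK pathway targets rose in 16 and fell in 2 of 19 (median 1.18; camera adjusted p = 1.2e-10, and adjusted p = 0.0563 with an estimated correlation). Egr1 rose from 0.43 ± 0.012 to 2.87 ± 0.13 CPM. TGF-β and BMP targets had 3 up and 6 down of 13 (adjusted p = 2.35e-08, and adjusted p = 0.0563 with an estimated correlation), with Id4 down 3.72-fold beside the Lefty genes. The list did not move as a whole, since the BMP target Id1 rose 7.85-fold, from 2.69 ± 0.16 to 21.2 ± 2.1 CPM. Levels of Id2 and Id3 were also higher in each long 2i library than in any first 2i library. Of 10 neuroectoderm genes 5 rose and 1 fell (median 1.06, or 0.24 with bounds; camera adjusted p = 7.58e-06, and adjusted p = 0.0563 with an estimated correlation), including Tubb3, a neuronal β-tubulin, from 6.46 ± 0.39 to 33.7 ± 3.5 CPM. 11 SRF and YAP targets rose and 2 fell of 18 (adjusted p = 0.0013, and adjusted p = 0.128 with an estimated correlation), with the secreted matrix proteins Cyr61 and Ctgf up 4.8-fold and 2.93-fold. DNA methylation and retroelement genes counted 11 up and 3 down of 29 (adjusted p = 0.0013, and adjusted p = 0.0567 with an estimated correlation).

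Cholesterol synthesis rose in 15 and fell in 2 of 24 genes (adjusted p = 0.00203, and adjusted p = 0.0589 with an estimated correlation). p53 targets had 14 up and 4 down of 20 (adjusted p = 0.0144, and adjusted p = 0.185 with an estimated correlation). Oxidative phosphorylation had 41 up and 14 down of 79 (adjusted p = 0.0144, and adjusted p = 0.427 with an estimated correlation) and glycolysis 5 up and 13 down of 21 (adjusted p = 0.0339, and adjusted p = 0.378 with an estimated correlation). 9 of 17 Hox genes rose and 8 did not pass (adjusted p = 0.0339, and adjusted p = 0.153 with an estimated correlation). Paternally expressed imprinted genes counted 12 up and 7 down of 26 (adjusted p = 0.0287, and adjusted p = 0.128 with an estimated correlation), with Mest up 9.42-fold and Dio3 down 16.4-fold. Formative genes had 6 up and 5 down of 17, a median of 0 and a mean of 0.45 (adjusted p = 0.0287, and adjusted p = 0.226 with an estimated correlation).

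Lists that camera did not call included pluripotency (9 up, 16 down of 28; adjusted p = 0.129), with Klf2 down 2.17-fold. Also not called were Wnt targets (10 up, 3 down of 22; adjusted p = 0.424) and germline genes (13 up, 11 down of 32; adjusted p = 0.0565; median -0.18, mean 0.14). The edgeR call for Klf2 was lost with only the groups compared (adjusted p = 0.0892), without replicate 1 of long 2i (adjusted p = 0.0927) and without replicate 2 of first 2i (adjusted p = 0.0873). Fkbp6, a meiotic gene, rose from 9.26 ± 0.33 to 92.9 ± 0.25 CPM. Y-linked genes diverged, 2 up and 3 down of 6 (adjusted p = 0.686; median -0.33, mean 0.63): Kdm5d rose from 2.68 ± 0.35 to 13.4 ± 0.0026 CPM and Usp9y from 0.874 ± 0.62 to 10.1 ± 0.024 CPM. Markers of blood and endothelium (3 up, 2 down of 10; adjusted p = 0.686) included Esam, an endothelial adhesion molecule, at 5.17 ± 0.45 from 0.285 ± 0.13 CPM, and fibroblast markers counted 2 up and 3 down of 11 (adjusted p = 0.686). Adjusted over the list alone, Wnt components had 14 up and 11 down (13 and 11 over all genes), paternally expressed genes 8 down and germline genes 12 down. 2-cell-like genes had 3 down (2 up and 4 down over all genes) and TGF-β and BMP targets 7 down. Other counts were the same.

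Long 2i against original serum combined the first response with what followed. Cyp1a1 was at least 668-fold higher (49.9 ± 2.3 CPM against no counts in serum), and Nefm and Nefl rose from 0.246 ± 0.13 and 1.4 ± 0.16 to 127 ± 5.8 and 138 ± 2.5 CPM. Axin2 and Sp5 were 27.7-fold and 238-fold higher, at 74.1 ± 1.5 and 25.1 ± 6.5 CPM. The long noncoding RNA Miat, at 12.7 ± 1.1 CPM in serum, was at least 152-fold lower and Cdh22, a cadherin at 6.71 ± 0.9 CPM in serum, at least 80.2-fold lower, both with no counts in long 2i. Lefty1 fell from 156 ± 12 to 0.734 ± 0.22 CPM and Nos3, the endothelial nitric oxide synthase, from 44.1 ± 5.3 to 0.168 ± 0.013 CPM.

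With edgeR and Benjamini-Hochberg adjustment 9804 genes changed (68.9%), 4986 higher and 4818 lower, 3699 by at least 2-fold. Sox2 fell 2.07-fold and Pou5f1 1.32-fold, Nanog rose to 887 ± 29 from 719.7 ± 14 CPM, and Esrrb did not pass (977 ± 36 against 1016 ± 45 CPM). Dnmt3l was 4.43-fold and Dnmt3a 2.94-fold below serum, Dnmt3b and Meg3 were 1.22-fold and 2.35-fold above it, and H19 read 4.69 ± 0.67 CPM in serum and 3 counts in long 2i. Xlr5a, at 6.57 ± 0.49 CPM in long 2i, belongs to a family of near-identical copies and is uncertain.

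ERK pathway targets fell in 16 and rose in 2 of 19 (camera adjusted p = 4.02e-11, and adjusted p = 0.0262 with an estimated correlation). Of 21 glycolysis genes 16 fell and 4 rose (adjusted p = 9.38e-16, and adjusted p = 0.0262 with an estimated correlation), with Ldha, lactate dehydrogenase A, down 6.64-fold. 23 of 24 cholesterol synthesis genes rose and 1 fell (adjusted p = 4.57e-08, and adjusted p = 0.0262 with an estimated correlation). TGF-β and BMP targets fell in 9 and rose in 1 of 13 (adjusted p = 1.26e-11, and adjusted p = 0.0262 with an estimated correlation). p53 targets rose in 18 and fell in 2 of 20 (adjusted p = 1.51e-06, and adjusted p = 0.0447 with an estimated correlation), the exceptions including Pmaip1, down 34.7-fold. 14 of 17 Hox genes rose and 3 did not pass (median 5.49, or 3.57 with bounds; adjusted p = 0.00058, and adjusted p = 0.0447 with an estimated correlation).

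Other calls were lost with an estimated correlation. They covered neuroectoderm (5 up, 4 down of 10; adjusted p = 0.000942, and adjusted p = 0.124 with an estimated correlation) and pluripotency (5 up, 18 down of 28; adjusted p = 0.00902, and adjusted p = 0.133 with an estimated correlation). Germline genes (16 up, 12 down of 32; adjusted p = 0.0134, and adjusted p = 0.124 with an estimated correlation) and SRF and YAP targets (13 up, 2 down of 18; adjusted p = 0.0134, and adjusted p = 0.145 with an estimated correlation) were the next. The same held for endoderm (4 up, 10 down of 19; adjusted p = 0.0248, and adjusted p = 0.124 with an estimated correlation) and fibroblast markers (1 up, 6 down of 11; adjusted p = 0.0248, and adjusted p = 0.133 with an estimated correlation). The last of these were Y-linked genes (5 up of 6; adjusted p = 0.0248, and adjusted p = 0.124 with an estimated correlation) and formative genes (6 up, 9 down of 17; adjusted p = 0.0258, and adjusted p = 0.135 with an estimated correlation). Plagl1 was 16-fold higher than in serum, Fkbp6 rose to 92.9 ± 0.25 CPM and Hoxc12 was at least 49.8-fold higher. With p-values adjusted over the list alone, glycolysis had 5 up, Y-linked genes 1 down and 2-cell-like genes 2 up and 1 down (2 and 2 over all genes). Ribosomal proteins had 14 up and 12 down (15 and 12) and oxidative phosphorylation 31 up and 15 down (32 and 16). Other counts were the same.

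Whether expression after long 2i moved back in serum was addressed by 6 passages of return. Axin2 fell 9.52-fold from 74.1 ± 1.5 to 7.77 ± 0.13 CPM, and Nefm and Nefl fell from 127 ± 5.8 and 138 ± 2.5 to 0.376 ± 0.13 and 2.15 ± 0.45 CPM. Spry4 rose 22.9-fold to 451 ± 14 CPM, Lefty1 and Lefty2 to 119.6 ± 13 and 340 ± 1.5 CPM, and Dnmt3l to 392 ± 20 CPM. Cdh22 and Miat, with no counts in long 2i, were at least 100.4-fold and 63.5-fold higher, at 8.4 ± 0.5 and 5.31 ± 0.86 CPM.

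By the edgeR test with Benjamini-Hochberg adjustment 10153 genes changed (71.4%), 5040 higher and 5113 lower, 3808 by at least 2-fold. Pou5f1 rose 1.3-fold and Sox2 1.87-fold, to 1191 ± 40 and 736 ± 11 CPM, and Nanog (925 ± 33 against 887 ± 29 CPM) and Esrrb (1009 ± 31 against 977 ± 36 CPM) did not pass. Dnmt3a rose 3.01-fold, Dnmt3b fell 1.77-fold and Meg3 2.38-fold, and H19 read 2.31 ± 0.24 CPM against 3 counts in long 2i. Pof1b was at least 110.3-fold lower after the return, from 6.7 ± 0.45 CPM, and Cyp1a1 fell from 49.9 ± 2.3 to 0.131 ± 0.12 CPM.

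Cholesterol synthesis fell in 23 and rose in 1 of 24 genes (camera adjusted p = 3.1e-12, and adjusted p = 0.0115 with an estimated correlation). ERK pathway targets rose in 16 and fell in 2 of 19 (adjusted p = 2.33e-09, and adjusted p = 0.0334 with an estimated correlation). Glycolysis rose in 16 with 4 down of 21 (adjusted p = 6.69e-15, and adjusted p = 0.0334 with an estimated correlation), including Pdk1, a pyruvate dehydrogenase kinase, up 7.29-fold. TGF-β and BMP targets counted 8 up and 2 down of 13 (adjusted p = 1.76e-07, and adjusted p = 0.0623 with an estimated correlation). p53 targets and cell-cycle inhibitors fell in 16 and rose in 3 of 20 (adjusted p = 0.000341, and adjusted p = 0.103 with an estimated correlation), with Cdkn2a down 23.1-fold and Pmaip1 up 44.8-fold. SRF and YAP targets fell in 15 and rose in 2 of 18 (adjusted p = 0.00066, and adjusted p = 0.103 with an estimated correlation). In all, 14 of 17 Hox genes fell (adjusted p = 0.000808, and adjusted p = 0.103 with an estimated correlation).

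Among the lists of other lineages, endoderm genes rose in 13 and fell in 5 of 19 (adjusted p = 0.00361, and adjusted p = 0.087 with an estimated correlation), among them Col4a1 at 167 ± 12 CPM. Fibroblast markers rose in 7 of 11 (adjusted p = 0.00392, and adjusted p = 0.103 with an estimated correlation), among them Thy1 at 22.3 ± 1.2 CPM. Neuroectoderm genes had 4 up and 5 down of 10 (adjusted p = 0.000834, and adjusted p = 0.103 with an estimated correlation), and pluripotency genes 16 up and 5 down of 28 (adjusted p = 0.0129, and adjusted p = 0.179 with an estimated correlation). Trophectoderm (6 up, 7 down of 16), primitive streak and mesoderm (5 up, 4 down of 13) and blood and endothelial genes (5 up, 2 down of 10) were not called (each adjusted p = 0.772). 2-cell-like genes rose in 14 and fell in 2 of 17 (median 4.18, or 3.1 with bounds; adjusted p = 0.386). Zscan4c and Zscan4d, near-identical copies whose split of reads is uncertain, were at least 20-fold and 27.6-fold higher. Imprinted Plagl1 fell 7.79-fold, maternally expressed Phlda2 rose from 0.264 ± 0.37 to 13.9 ± 0.52 CPM and Dppa3 fell from 18.6 ± 0.5 to 0.398 ± 0.3 CPM. In these libraries Rn45s stood at 2496 and 15480 CPM. Adjusted over the list alone, formative genes had 9 up and 6 down (9 and 5 over all genes) and germline genes 16 up and 12 down (15 and 12). Ribosomal proteins had 9 up and 24 down (11 and 27), and other counts were the same.

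Serum return was then compared with original serum, whose passage number is not given in the labels. In this comparison earlier 2i culture cannot be told apart from passage number or time in culture. Axin2 stayed 2.91-fold above the original level, at 7.77 ± 0.13 against 2.68 ± 0.48 CPM. Gata6, a transcription factor of endoderm, rose 5.19-fold to 5.99 ± 0.15 CPM, Pdgfra, a receptor known from primitive endoderm, to 2.98 ± 0.66 CPM from 0.576 ± 0.07 CPM and Sox1, a neural transcription factor, to 25.3 ± 3.8 from 12.8 ± 0.21 CPM. Of 32 germline genes known for promoter methylation 25 were higher and 2 lower, and of 17 2-cell-like genes 14 were higher. The BMP target Id3 fell 3.18-fold to 14.1 ± 2.7 CPM.

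The edgeR test with Benjamini-Hochberg adjustment called 4407 genes (31%), 2347 higher and 2060 lower, 459 by at least 2-fold. The count was 2437 without replicate 1 of serum return and 2822 without replicate 2 of original serum. Pou5f1, Esrrb, Dnmt3a, Dnmt3l and Meg3 did not pass (log2 fold changes -0.03 ± 0.05, -0.01 ± 0.05, 0.04 ± 0.07, 0.08 ± 0.05 and -0.02 ± 0.06, ± SE). Nanog rose 1.29-fold and Sox2 fell 1.11-fold, Dnmt3b 1.45-fold and H19 from 4.69 ± 0.67 to 2.31 ± 0.24 CPM. In edgeR, Sox2 was not called without replicate 1 of serum return (adjusted p = 0.122) or without replicate 1 or 2 of original serum (adjusted p = 0.0711 and 0.0741). H19 was not called by edgeR without replicate 1 of original serum (adjusted p = 0.0639) or in DESeq2 (adjusted p = 0.0504). The largest increases besides Gata6, among genes with a mean of at least 5 CPM in either group, were Vldlr, a lipoprotein receptor, at 8.58 ± 0.092 from 1.83 ± 0.22 CPM and Trim52 at 7.92 ± 0.67 from 1.74 ± 0.035 CPM. Next came Zfp951 at 10.9 ± 1 from 3.13 ± 0.52 CPM and Aim2, a sensor of cytosolic DNA, at 15.4 ± 1.3 from 4.56 ± 0.92 CPM. Kcnq1ot1, an imprinted noncoding RNA antisense to Kcnq1, fell 3.63-fold, Lad1 3.14-fold, Id4 2.33-fold and Rimbp2 4.03-fold. Whether counting used strand is not given, so reads of Kcnq1ot1 and its antisense partner cannot be separated.

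The germline list had camera adjusted p = 1.69e-11, and adjusted p = 0.0298 with an estimated correlation, and the 2-cell-like list had adjusted p = 7.36e-09, and adjusted p = 0.0815 with an estimated correlation (median 3.35, or 3.26 with bounds). Zscan4d read 2.31 ± 0.64 CPM against 3 counts in original serum and Gm5662 2.11 ± 0.042 CPM against 3 counts. Cholesterol synthesis fell in 13 of 24 genes and the other 11 did not pass (adjusted p = 2.75e-06, and adjusted p = 0.0298 with an estimated correlation). TGF-β and BMP targets counted 1 up and 6 down of 13 (adjusted p = 3.06e-06, and adjusted p = 0.105 with an estimated correlation). p53 targets rose in 10 and fell in 2 of 20 (adjusted p = 0.000672, and adjusted p = 0.142 with an estimated correlation), including Cdkn1a, up 1.73-fold to 32.4 ± 2.4 CPM.

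SRF and YAP targets had 1 up and 7 down of 18 (adjusted p = 0.00943, and adjusted p = 0.152 with an estimated correlation). Oxidative phosphorylation had 5 up and 22 down of 79 (adjusted p = 0.00975, and adjusted p = 0.454 with an estimated correlation) and ribosomal proteins 4 up and 11 down of 79 (adjusted p = 0.033, and adjusted p = 0.437 with an estimated correlation). Endoderm genes rose in 8 and fell in 2 of 19 (adjusted p = 0.0131, and adjusted p = 0.152 with an estimated correlation). Fibroblast markers rose in 4 of 11 (adjusted p = 0.033, and adjusted p = 0.152 with an estimated correlation) and Y-linked genes in 4 of 6 (adjusted p = 0.0264, and adjusted p = 0.152 with an estimated correlation). Rn45s stood at 4708 and 5445 CPM in original serum and at 2496 and 15480 CPM after the return. Wnt targets were not called (2 up, 5 down of 22; adjusted p = 0.545; median 0.04, camera downward), nor were ERK targets (1 up, 6 down of 19; adjusted p = 0.237). When adjusted over the list alone, ERK targets had 3 up and 6 down, germline genes 26 up, SRF and YAP targets 2 up and 9 down and ribosomal proteins 9 down. Pluripotency genes had 8 down (5 up and 6 down over all genes), Wnt components 7 down (4 and 6) and DNA methylation genes 4 up and 8 down (3 and 7). For glycolysis there were 6 up (5 and 6), for Hox genes 1 up (2 over all genes), and the 1 primitive streak gene that had fallen did not pass. Other counts were the same.

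A second exposure to 2i was then compared with serum return. Axin2 rose 11-fold from 7.77 ± 0.13 to 85.3 ± 0.0016 CPM, Sp5 to 24.5 ± 4.5 CPM from 0.129 ± 0.081, and Nkx1-2 was at least 242-fold higher. Spry4 fell 51.5-fold to 8.74 ± 0.51 CPM, Etv4 12.7-fold, Dnmt3l 11.2-fold to 35.1 ± 2.2 CPM and Dnmt3a 3.06-fold. The immediate-early genes Fos and Fosb rose from 6.34 ± 0.87 and 0.213 ± 0.1 to 131 ± 0.8 and 39 ± 0.75 CPM, and Egr1, named here after its values were seen, rose from 28.1 ± 0.54 to 113 ± 4.3 CPM.

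By edgeR with Benjamini-Hochberg adjustment 9335 genes changed (65.6%), 4598 higher and 4737 lower, 3133 by at least 2-fold. Nanog rose from 925 ± 33 to 1292 ± 3.8 CPM, Esrrb 1.27-fold and Pou5f1 1.13-fold, whereas Sox2 fell 1.2-fold, Dnmt3b 1.74-fold, Meg3 1.3-fold and H19 from 2.31 ± 0.24 to 0.161 ± 0.0037 CPM. Without replicate 2 of second 2i the edgeR call for Pou5f1 was lost (adjusted p = 0.054). Sp100, a nuclear body protein, was at least 113-fold higher (6.86 ± 0.22 CPM) and Lrrc15, a leucine-rich repeat protein, rose to 98.3 ± 1 from 0.756 ± 0.51 CPM. Among genes with a mean of at least 5 CPM in either group the largest decreases included the growth factor receptor Fgfr3 (from 53.3 ± 2.7 to 0.727 ± 0.28 CPM) and Calca, the calcitonin gene (19.8 ± 1.6 to 0.188 ± 0.042 CPM). Others were Cyp11a1, the first enzyme of steroid synthesis (15.9 ± 0.044 to 0.187 ± 0.034 CPM) and AU015836 (21 ± 0.72 to 0.294 ± 0.11 CPM).

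Cholesterol synthesis rose in 22 and fell in 1 of 24 genes (camera adjusted p = 8.39e-10, and adjusted p = 0.0204 with an estimated correlation). ERK pathway targets fell in 15 and rose in 3 of 19 (adjusted p = 1.04e-10, and adjusted p = 0.06 with an estimated correlation). Of 21 glycolysis genes 13 fell and 5 rose (adjusted p = 8.39e-10, and adjusted p = 0.0827 with an estimated correlation), with Pdk1 down 9.58-fold and Slc2a1 5.79-fold. Endoderm genes fell in 13 and rose in 4 of 19 (adjusted p = 0.000124, and adjusted p = 0.0827 with an estimated correlation), including Sox7, from 36.5 ± 0.54 to 0.485 ± 0.24 CPM, and Col4a1, to 2.6 ± 0.4 CPM. Wnt targets rose in 14 and fell in 5 of 22 (adjusted p = 0.00321, and adjusted p = 0.41 with an estimated correlation). Formative genes counted 6 up and 10 down of 17 (adjusted p = 0.00155, and adjusted p = 0.152 with an estimated correlation).

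16 of 17 Hox genes rose (median 3.29, or 2.5 with bounds; adjusted p = 0.00188, and adjusted p = 0.14 with an estimated correlation). Maternally expressed imprinted genes fell in 14 and rose in 2 of 23 (adjusted p = 0.0077, and adjusted p = 0.165 with an estimated correlation), and fibroblast markers in 6 of 11 (adjusted p = 0.015, and adjusted p = 0.165 with an estimated correlation). For SRF and YAP targets there were 8 up and 3 down of 18 (adjusted p = 0.0344, and adjusted p = 0.273 with an estimated correlation). Paternally expressed Dio3 rose to 20 ± 2 from 0.299 ± 0.17 CPM and Peg10 fell 7.1-fold. Nefl and Nefm rose to 65.5 ± 4.2 and 17.6 ± 0.52 CPM, and Pmaip1 fell 24.5-fold. Pluripotency genes were not called (14 up, 13 down of 28; adjusted p = 0.601; median 0.13, mean -0.13). Adjusted over the list alone, ERK targets had 4 up, 2-cell-like genes 8 up (9 up and 1 down over all genes), ribosomal proteins 25 up and 2 down (28 and 3) and oxidative phosphorylation 34 up (37 and 8). Other counts were the same.

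Second 2i was set against first 2i, the same medium after 4 to 5 and 5 to 6 passages, to see how far the endpoint differed. Per the labels, second 2i cells had also been through an earlier 2i culture and a return to serum, so earlier exposure cannot be told apart from time in culture. Egr1 was 259-fold higher in second 2i (113 ± 4.3 against 0.43 ± 0.012 CPM), Fos 75.1-fold (131 ± 0.8 against 1.74 ± 0.12 CPM) and Fosb rose as well (39 ± 0.75 against 0.0945 ± 0.065 CPM). Dnmt3l was 8.34-fold, Dnmt3b 2.03-fold, Spry4 5.07-fold and Etv4 4.85-fold higher. Cyp1a1 fell from 6.7 ± 0.65 to 0.405 ± 0.27 CPM, Dppa3 from 12.6 ± 0.53 to 1.41 ± 0.46 CPM and Krt7 from 8.58 ± 0.43 to 0.78 ± 0.28 CPM. Axin2 rose from 68.7 ± 2.6 to 85.3 ± 0.0016 CPM.

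Quasi-likelihood testing in edgeR with Benjamini-Hochberg adjustment called 5357 genes (37.7%), 2570 higher and 2787 lower, 943 by at least 2-fold. The count was 3556 without replicate 2 of second 2i. The homeobox genes Tlx2 and Cdx1 rose to 22.5 ± 4.5 and 46.2 ± 7.2 CPM from 1.99 ± 0.9 and 5.99 ± 0.41 CPM. Calb2, a calcium-binding protein of neurons, fell 8.66-fold, the homeobox gene Rhox9 fell to 0.857 ± 0.056 from 8.22 ± 0.68 CPM and Meg3 fell 1.55-fold. Pou5f1, Nanog and Esrrb were 1.26-fold, 1.16-fold and 1.12-fold higher. Sox2 and Dnmt3a were 1.29-fold and 1.38-fold lower, and H19 read 0.161 ± 0.0037 CPM against 1 count in first 2i and did not pass. Esrrb lost its edgeR call without replicate 1 of first 2i (adjusted p = 0.114) or replicate 2 of second 2i (adjusted p = 0.13).

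Of 19 ERK targets 12 were higher and 7 did not pass (median 0.79; camera adjusted p = 5.49e-27, and adjusted p = 0.012 with an estimated correlation). 15 of 17 2-cell-like genes were higher (adjusted p = 3.21e-10, and adjusted p = 0.0595 with an estimated correlation), among them Gm5662 at 4.08 ± 0.47 and Gm8300 at 3.63 ± 1 CPM. p53 targets and cell-cycle inhibitors fell in 11 and rose in 3 of 20 (adjusted p = 5.78e-05, and adjusted p = 0.0951 with an estimated correlation), including Cdkn2a, down 1.89-fold, and Ccng1, cyclin G1, down 1.7-fold. Wnt targets rose in 7 and fell in 1 of 22 (adjusted p = 0.000536, and adjusted p = 0.257 with an estimated correlation). DNA methylation and retroelement genes had 12 up and 5 down of 29 (adjusted p = 0.00138, and adjusted p = 0.0846 with an estimated correlation), with Tet2, a 5-methylcytosine oxidase, up 2.32-fold.

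Ribosomal proteins, uncertain because of pseudogenes, rose in 29 and fell in 4 of 79 (adjusted p = 0.000223, and adjusted p = 0.192 with an estimated correlation). Oxidative phosphorylation rose in 33 and fell in 3 of 79 (adjusted p = 0.00138, and adjusted p = 0.349 with an estimated correlation). Glycolysis rose in 11 with 5 down of 21 (adjusted p = 0.0343, and adjusted p = 0.365 with an estimated correlation). Neuroectoderm genes counted 5 up and 1 down of 10 (median 0.57, or 0.42 with bounds; adjusted p = 0.0148, and adjusted p = 0.192 with an estimated correlation). There were 8 SRF and YAP targets up and 3 down of 18 (adjusted p = 0.0245, and adjusted p = 0.221 with an estimated correlation). Hox genes counted 6 up and 1 down of 17 (adjusted p = 0.0379, and adjusted p = 0.192 with an estimated correlation). Cyr61 and Ctgf were 3.23-fold and 2.26-fold higher, and Otx2, an epiblast transcription factor, 3.09-fold lower. Adjusted over the list alone, ERK targets had 1 down, 2-cell-like genes 16 up, p53 targets 12 down, ribosomal proteins 33 up and oxidative phosphorylation 34 up. DNA methylation genes had 13 up, neuroectoderm 2 down and SRF and YAP targets 4 down. Wnt components had 10 up and 7 down (9 and 6 over all genes) and germline genes 11 up and 10 down (9 and 8). Endoderm genes had 8 up and 4 down (6 and 4) and blood and endothelial markers 4 up and 2 down (3 and 2), and other counts were the same.

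**Figure D2:**
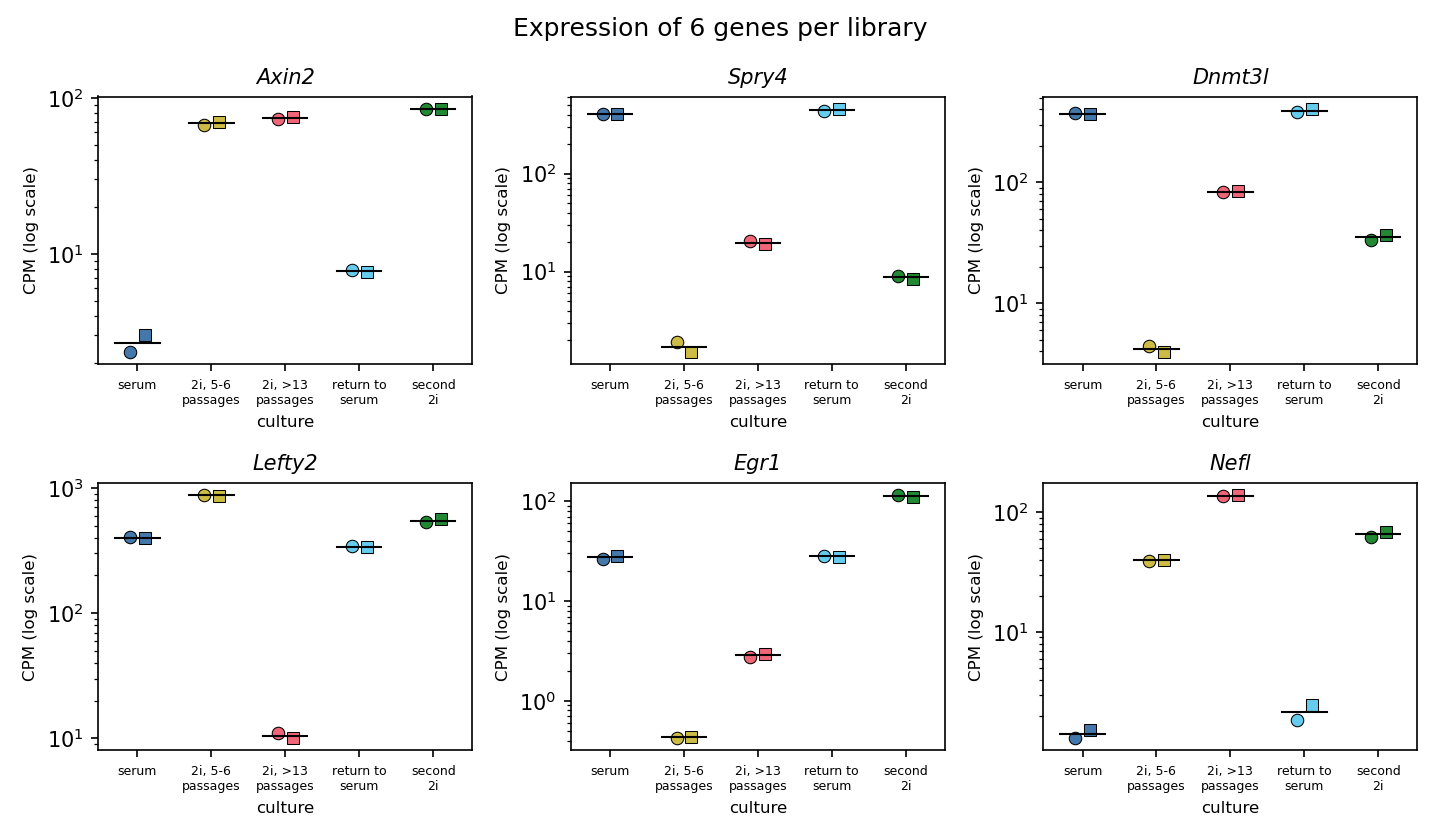
CPM on a log scale of Axin2, Spry4, Dnmt3l, Lefty2, Egr1 and Nefl in each library (circle, replicate 1; square, replicate 2), with the group mean as a line, over the 5 cultures. Egr1 was higher in second 2i (113 ± 4.3 CPM) than in any other culture, and Lefty2 was lowest in long 2i (10.5 ± 0.68 CPM).

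Whether the response to 2i differed between the first and second exposure was tested as the difference of the 2 responses, which share no library. Across 14220 genes the responses had a Pearson correlation of 0.83 and a Spearman correlation of 0.737 (genes are not independent replicates). Of 7328 genes changed in both, 6704 moved the same way (91.5%) and 624 in opposite directions. Independent lists of these sizes would share 1615 higher and 1651 lower genes, and 3316 and 3388 were observed. Egr1, Fos and Fosb had the largest upward differences between responses among genes with a mean of at least 5 CPM in any group, at 7.99 ± 0.17, 5.88 ± 0.21 and 7.78 ± 1.39 on the log2 scale (± SE), followed by Robo4 (3.29, or 4.24 without replicate 2 of first 2i) and Mical2, an actin-oxidising enzyme. Mical2 stood at 5.99 ± 0.08 CPM in serum and 3 counts in first 2i, and at 2.93 ± 0.27 CPM in serum return and 0.351 ± 0.2 CPM in second 2i.

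The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment found a different response for 5598 genes (39.4%), 2617 upward and 2981 downward, 1236 by at least 2-fold. Calb2 (-4.45), Taf7l, a testis TFIID subunit (-3.68), Calr4 (-3.17) and Ctnnd2, a δ-catenin (-3.12), differed downward. The fold of Axin2 was smaller in the second exposure (difference -1.23 ± 0.15), which started and ended higher (7.77 ± 0.13 to 85.3 ± 0.0016 CPM, against 2.68 ± 0.48 to 68.7 ± 2.6 CPM in the first). Dnmt3l and Dnmt3b differed upward, by 2.98 ± 0.11 and 1.56 ± 0.09. Pou5f1 (0.36 ± 0.07), Esrrb (0.18 ± 0.07) and H19, with 1 count in first 2i, differed upward and Sox2 (-0.22 ± 0.06), Dnmt3a (-0.51 ± 0.12) and Meg3 (-0.62 ± 0.08) downward, and Nanog (-0.15 ± 0.06) did not pass but did without replicate 2 of serum return (edgeR adjusted p = 0.0389). In edgeR the difference for Fosb rested on replicate 2 of serum (a fitted 3.35, adjusted p = 0.928 without it) and that for Mical2 on replicate 1 of second 2i (adjusted p = 0.0653). The edgeR calls for Esrrb, H19 and Sox2 were each lost when single libraries were left out, with adjusted p up to 0.204, 0.144 and 0.068, and H19 was not called in DESeq2 (adjusted p = 0.0622).

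The response of ERK pathway targets differed upward in 12 of 19, and 7 did not pass (median difference 0.69; camera adjusted p = 2.36e-20, and adjusted p = 0.0318 with an estimated correlation). The differences for DNA methylation genes (12 upward, 6 downward of 29; adjusted p = 0.000318), p53 targets (3 upward, 14 downward of 20; adjusted p = 2.15e-07) and cholesterol synthesis (13 upward and 11 not passing of 24; adjusted p = 2.64e-05) were called, and each had adjusted p = 0.0409 with an estimated correlation. Ribosomal proteins (30 upward, 2 downward of 79; adjusted p = 2.64e-05, and adjusted p = 0.143 with an estimated correlation) differed upward. Oxidative phosphorylation (36 upward, 2 downward of 79; adjusted p = 2.64e-05, and adjusted p = 0.272 with an estimated correlation) did so too.

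SRF and YAP targets (7 upward, 4 downward of 18; adjusted p = 0.00242, and adjusted p = 0.143 with an estimated correlation) were also called. So were Wnt targets (7 upward, 2 downward of 22; adjusted p = 0.0131, and adjusted p = 0.359 with an estimated correlation) and TGF-β and BMP targets (6 upward, 2 downward of 13; adjusted p = 0.0471, and adjusted p = 0.321 with an estimated correlation). Germline genes (3 upward, 15 downward of 32; adjusted p = 0.0131, and adjusted p = 0.227 with an estimated correlation) differed, as did pluripotency genes (10 upward, 8 downward of 28; adjusted p = 0.0471, and adjusted p = 0.302 with an estimated correlation). The 17 2-cell-like genes gave adjusted p = 0.766, with a median of 0.15 and a mean of -0.12. In counts adjusted over the list alone, pluripotency genes had 9 downward, germline genes 4 upward and 17 downward and oxidative phosphorylation 37 upward and 4 downward. Neuroectoderm had 2 downward (3 upward and 1 downward over all genes), glycolysis 10 upward (9 and 4) and Hox genes 2 upward and 1 downward (3 and 3). Other counts were the same.

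**Figure D3:**
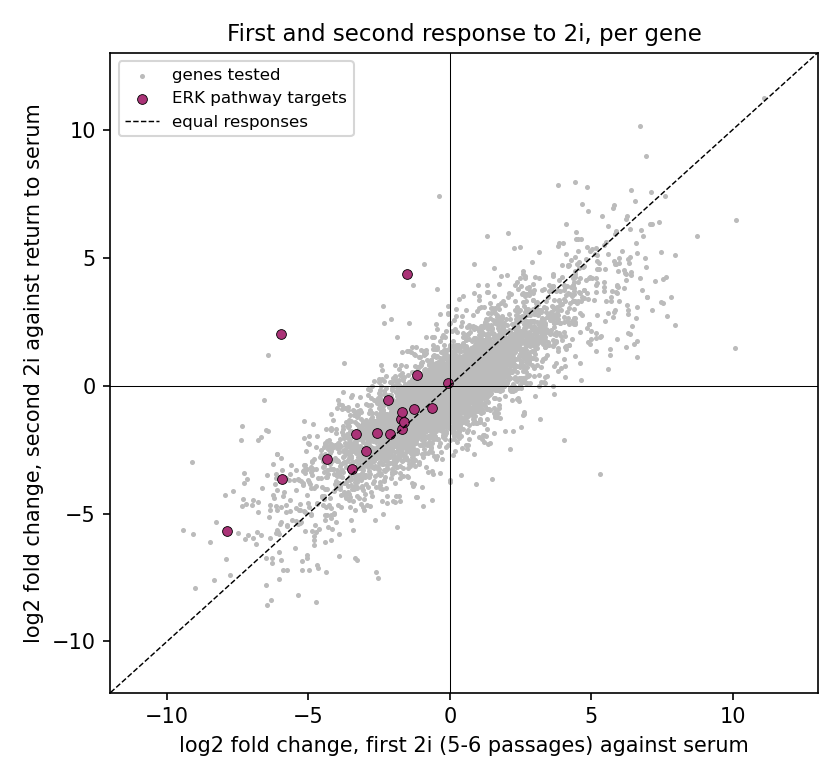
Log2 fold change of each tested gene in the first (x axis, 2i for 5 to 6 passages against serum) and second (y axis, second 2i against serum return) exposure, with ERK pathway targets marked and a dashed line at equal responses. The 2 responses had a Pearson correlation of 0.83 across genes, which does not measure closeness to the line, and 5598 of 14220 genes responded differently. Of 19 ERK pathway targets 12 lie significantly above the line.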

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

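All tests of explanations in this part were chosen only after the results were seen, and the gene sets or limits of the immediate-early, Zscan4, neural and scaling tests were changed after a first version had been seen. The difference between the second and the first response to 2i was a planned test. It stood out because 5598 genes differed between the 2 exposures (edgeR, 39.4% of genes tested).

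Egr1 and Fos, immediate-early genes, went opposite ways in the 2 exposures (log2 changes of -5.98 in the first and 2.01 in the second for Egr1, and -1.52 and 4.36 for Fos), so that the second response minus the first was 7.99 and 5.88. For Fosb, another such gene, it was 7.78 (a fitted 3.35 and not called in edgeR without replicate 2 of serum, since the other serum library held no counts of it), and the ERK pathway targets as a list differed upward (camera adjusted p = 2.36e-20). Whether weaker inhibition of the ERK pathway was the whole cause for these 3 genes is not decided. Of the 3 genes 3 passed as higher in second 2i than in serum return. They were chosen for a difference that includes this comparison, and the test assumes that a level under inhibitor cannot exceed that in serum. For other ERK pathway targets weaker inhibition may be a candidate explanation: 10 of 17 were higher in second than in first 2i with none called lower, and 15 of 17 were still below serum return. Levels above first 2i were not particular to the second exposure, since in long 2i 16 of the 19 ERK pathway targets were higher than in first 2i and 2 lower. A general immediate-early response, as handling at harvest (not described in the labels) could give, stays open, since 14 of 24 other immediate-early genes were higher and 4 lower (median 0.59), as does an untested biological difference in signalling after the earlier 2i culture. Rises over first 2i were not particular to second 2i in this set either. In long 2i, for example, Gadd45b (log2 fold change 2.62), Cyr61 (2.26) and Jun (1.38) passed as higher, and Atf3, Klf4 and Sik1 as lower. Against serum return, second 2i was lower for Junb (-1.02), Maff (-1.58) and Fosl2 (-3.53) and higher for Jun (1.59) and Cyr61 (1.88). Junb, Ier3 and Myc also stand among the ERK pathway targets.

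Of 17 2-cell-like genes 14 were higher in serum return than in original serum and 3 did not pass (camera adjusted p = 7.36e-09, and adjusted p = 0.0815 with an estimated correlation), and the difference between the responses was not called for this list. Cells carried over from long 2i are argued against, since 0 of the 14 members that rose had a higher mean in long 2i than in serum return. Reads moving between near-identical Zscan4 copies are argued against as well, since the summed CPM of all 6 Zscan4 genes was higher in each of the 4 library pairs, by at least 3.87 on the log2 scale (0.4 ± 0.024 CPM in serum, 7.87 ± 2.5 in serum return, 6.87 ± 0.69 in second 2i). The sum over the whole list was uninformative (smallest log2 ratio 0.04), since Eif1ad held 98.3% of it in serum. An exchange with reads aligned to more than 1 place stays open, and 10 of the 14 genes lie outside Zscan4. A change left by the earlier 2i culture was not tested and cannot be told apart from time in culture.

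The neurofilament genes Nefl and Nefm were higher in long than in first 2i. Differentiated neural cells in the culture cannot be told apart from a change within the stem cells, since 3 of 8 other neuroectoderm genes were higher, 1 was lower (Map2, -0.59) and their median was 0.24 (0.07 with bounds). The 3 were Tubb3 (2.38 on the log2 scale), Pax6 (1 count in first 2i) and Nes (0.33). Nes was not called in DESeq2, nor without replicate 1 or 2 of long 2i or replicate 2 of first 2i. Pax6 stood at 2.55 CPM and Tubb3 at 33.7 CPM in long 2i. Unlike scaling of the libraries as the whole cause of both rises is argued against, since scaling moves all genes alike and Nefm rose by 3.16 ± 0.13 (SE) more than Nefl on the log2 scale.

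Other results stood out for the same planned test of the 2 responses and are given as values. Downward differences on the log2 scale were those of Axin2 (-1.23), Calb2 (-4.45), Calr4 (-3.17), Ctnnd2 (-3.12), Taf7l (-3.68), Dnmt3a (-0.51), Meg3 (-0.62) and Sox2 (-0.22). Cyp1a1 differed by -8.63, a fitted value that depends on the prior count because original serum held no counts of it. The value was -7.09 without replicate 1 of serum return, where the edgeR call was lost, and -9.56 without replicate 1 of second 2i. Upward differences were those of Dnmt3b (1.56), Dnmt3l (2.98), Robo4 (3.29), Pou5f1 (0.36) and Esrrb (0.18). H19 (3.49) and Mical2 (3.21) differed upward too, by fitted values that depend on the prior count because first 2i held 1 and 3 counts of them. H19 ranged from 2.63 to 5.8 when single libraries were left out, and Mical2 had 2.5 and was not called without replicate 1 of second 2i (edgeR adjusted p = 0.0653). Lists whose responses differed by camera were p53 targets (adjusted p = 2.15e-07), cholesterol synthesis, ribosomal proteins and oxidative phosphorylation (each 2.64e-05), and DNA methylation genes (0.000318). The others were SRF and YAP targets (0.00242), Wnt targets and germline genes (each 0.0131), and pluripotency genes and TGF-β and BMP targets (each 0.0471). With an estimated correlation adjusted p was 0.143 for ribosomal proteins and SRF and YAP targets, 0.272 for oxidative phosphorylation, 0.359 for Wnt targets, 0.227 for germline genes, 0.302 for pluripotency genes and 0.321 for TGF-β and BMP targets, none of them called. Outside the main measurement, records of reads aligned to more than 1 place made up 36.2% ± 0.42 of all records in first 2i and 35.4% ± 0.42 in long 2i (SD, n = 2). Serum return had 35% ± 0.42 and second 2i 35.8% ± 0.42, all above the 33.9% ± 0.67 of original serum.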

How the results depend on the processing

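All comparisons of settings in this part were planned except the fit without Rn45s, which was chosen only after the result was seen. The counts of changed genes stayed within 1.5 times of those reported under every planned setting of scaling, filter, tool and libraries in the fit, without Rn45s and with the block. Leaving out a library took them beyond that only in 2 comparisons. Leaving out each library in turn gave 9064 to 9198 genes for first 2i against serum, 7609 to 7871 for long against first 2i, 9012 to 9126 for long 2i against serum and 9239 to 9481 for serum return against long 2i. It gave 2437 to 3333 for serum return against serum, 8181 to 8438 for second 2i against serum return and 3556 to 4218 for second against first 2i, and 4371 to 5123 for the difference of responses. The 3 counts beyond 1.5 times were 2437 without replicate 1 of serum return and 2822 without replicate 2 of serum (serum return against serum), and 3556 without replicate 2 of second 2i (second against first 2i), each from 1 library fewer. DESeq2 called 9109, 7783, 8996, 9332, 3261, 8323, 4177 and 4517 genes in the same order. The other scaling moved the median of all genes by -0.018 to 0.014 on the log2 scale. Deviations of libraries of the same title series correlated at 0.099 to 0.168 over the 10 pairs of groups and principal component 5 separated the series, but nothing in the labels makes them pairs. With the series as a block (pairing by title) the counts were 10705, 9569, 10557, 10847, 6172, 10216, 6933 and 7080, and it called Nanog in the difference of responses (adjusted p = 0.00138), Mt2 in second against first 2i (0.00244) and Dnmt3l in serum return against serum (0.0402), with no other change of call among named genes.

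Of 255 results for named genes 232 kept their direction and their side of the threshold in every setting that gave a value (H19 was not tested for long or second against first 2i with only the groups compared). The cause was not tested for the rest. Directions reversed only for values not called, when a library was left out. The log2 fold changes then ranged from -2.32 to 3.87 for H19 in long against first 2i (fitted values that depend on the prior count, since neither group held more than 3 counts) and from -0.03 to 0.11 for Mt1 in second against first 2i. For serum return against serum they ranged from -0.01 to 0.09 for Dnmt3a, -0.05 to 0.04 for Esrrb, -0.09 to 0.05 for Meg3 and -0.06 to 0.01 for Pou5f1. With 1 and 3 counts of H19 in first and long 2i, a difference between them was not detectable at this depth.

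Camera called 87 of 200 list results, and the other scaling changed none of the 200. With an estimated correlation 69 calls were lost, and the cause was not tested. The lost calls for first 2i against serum had adjusted p of formative 0.13, DNA methylation and endoderm 0.146, p53 0.205, glycolysis and cholesterol 0.126. For long against first 2i they were formative 0.226, ERK, neuroectoderm and TGF-β/BMP 0.0563, paternal imprinted and SRF/YAP 0.128, DNA methylation 0.0567, p53 0.185, glycolysis 0.378, cholesterol 0.0589, Hox 0.153, oxidative phosphorylation 0.427. For long 2i against serum they were pluripotency and fibroblast 0.133, formative 0.135, germline, neuroectoderm, endoderm and Y-linked 0.124, SRF/YAP 0.145. For serum return against long 2i they were pluripotency 0.179, neuroectoderm, fibroblast, p53, SRF/YAP and Hox 0.103, endoderm 0.087, TGF-β/BMP 0.0623. For serum return against serum they were 2-cell-like 0.0815, endoderm, fibroblast, SRF/YAP and Y-linked 0.152, p53 0.142, TGF-β/BMP 0.105, ribosomal 0.437, oxidative phosphorylation 0.454. For second 2i against serum return they were formative 0.152, Wnt targets 0.41, ERK 0.06, maternal imprinted and fibroblast 0.165, endoderm and glycolysis 0.0827, SRF/YAP 0.273, Hox 0.14. For second against first 2i they were Wnt targets 0.257, DNA methylation 0.0846, 2-cell-like 0.0595, neuroectoderm, Hox and ribosomal 0.192, p53 0.0951, glycolysis 0.365, SRF/YAP 0.221, oxidative phosphorylation 0.349. For the difference of responses they were pluripotency 0.302, Wnt targets 0.359, germline 0.227, SRF/YAP and ribosomal 0.143, TGF-β/BMP 0.321, oxidative phosphorylation 0.272.

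The fry test was used in its directional form, which asks whether a list moves up or down as a whole, without comparing it with other genes. It called 67 more, and a list whose members move both ways can go uncalled. The calls are given without direction, which need not follow the members. For long against first 2i, 2-cell-like genes were called upward with 2 up, 4 down and a median of -1.19 (-0.09 with bounds). Germline genes were called upward there with a median of -0.18. For serum return against long 2i they were called downward with a median of 0.36. New calls for first 2i against serum had adjusted p of pluripotency 0.00041, Wnt targets 0.00814, maternal imprinted 4.19e-05, germline 0.000637, neuroectoderm 0.0181, streak 0.000301, trophectoderm 0.0462, fibroblast 7.43e-05, blood 0.00127, TGF-β/BMP 0.000207, Y-linked 6.91e-05, Hox 1.71e-05, ribosomal and oxidative phosphorylation 0.0163. For long against first 2i these were pluripotency 0.000576, maternal imprinted 0.000551, germline 0.000638, 2-cell-like 0.0453, streak 0.00283, endoderm 0.00444, ribosomal 0.00591. For long 2i against serum these were Wnt targets 0.00199, maternal imprinted 0.00233, paternal imprinted 2.8e-05, 2-cell-like 0.0092, streak 0.0058, blood 0.00666, oxidative phosphorylation 0.0145. For serum return against long 2i these were formative 4.43e-05, Wnt targets 0.000889, Wnt components, germline and blood 0.0336, maternal imprinted 0.00111, paternal imprinted 8.39e-06, DNA methylation 0.0331, 2-cell-like 0.00139, streak 0.0192, Y-linked 0.00031, ribosomal 0.0106, oxidative phosphorylation 0.00109. For serum return against serum these were formative 0.0183, paternal imprinted 0.0274, DNA methylation 0.0101, Hox 0.0218. For second 2i against serum return these were pluripotency 0.0121, Wnt components 0.00889, DNA methylation 0.000148, germline 0.042, 2-cell-like 0.00177, neuroectoderm 0.000583, streak 0.00226, blood 0.00825, TGF-β/BMP 0.0145, Y-linked 0.0031, ribosomal 0.00182, oxidative phosphorylation 0.00357. For second against first 2i these were pluripotency 0.0051, formative 0.0334, maternal imprinted 0.00471, streak 0.0484, fibroblast 0.0342, cholesterol 0.000531. For the difference of responses these were formative and maternal imprinted 0.00524, glycolysis 0.0134, Y-linked 0.00597. Directions reversed in fry for Wnt components in long against first 2i (adjusted p = 0.955), glycolysis in serum return against serum (0.968), TGF-β/BMP in second against first 2i (0.9) and paternal imprinted genes in the difference of responses (0.854), none of them called. The cause of changes with the block was not tested. Hox and Wnt components for long against first 2i then had adjusted p of 0.096 and 0.77 and Y-linked genes 0.689. Fibroblast and Y-linked genes for long 2i against serum had 0.062, fibroblast and glycolysis for serum return against serum 0.0544 and 0.914, and paternal imprinted genes for second 2i against serum return 0.827. Hox and TGF-β/BMP for second against first 2i had 0.0844 and 0.948, and TGF-β/BMP and blood for the difference of responses 0.0577 and 0.98. The values of 0.689 and above went with a reversed direction. Calls gained with the block were Y-linked for first 2i against serum (0.0246), pluripotency for long against first 2i (0.0231), cholesterol for second against first 2i (0.0412) and Y-linked for the difference of responses (0.0256).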

Other observations

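The genes and tests in this part were chosen only after the results were seen, and the rule of the receptor test was changed after a first version had been seen. Mt1, a metallothionein that binds zinc and copper, rose from 168 ± 7.1 CPM in serum to 455 ± 18 CPM in first 2i (log2 fold change 1.44) and Mt2 from 250.3 ± 10 to 833 ± 37 CPM (1.74). In serum return they stood at 94.7 and 156 CPM and in second 2i at 469 and 893 CPM, and neither passed between second and first 2i in edgeR. Ahr, the aryl hydrocarbon receptor, rose from 1.63 ± 0.13 to 13.5 ± 1.4 CPM in first 2i and stood at 13.7 CPM in long 2i, 1.35 in serum return and 6.28 in second 2i.

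Cyp1a1 is a target of that receptor, and whether other targets moved with it in first 2i was tested. Of 5 other targets tested 3 were higher (Cyp1b1, Ahrr and Nqo1) and 1 was lower (Tiparp, -0.92), so that an active receptor may account for the 3 but is not decided by a set that went both ways. Ahrr rose from 0.254 ± 0.16 to 4.28 ± 0.89 CPM and Nqo1 from 36 ± 3.7 to 172 ± 4.4 CPM, and Cyp1b1 was not called in DESeq2 (adjusted p = 0.118) or without replicate 1 of first 2i or replicate 2 of serum (edgeR adjusted p = 0.0958 and 0.0999). In second against first 2i the log2 fold changes were -4.04 for Cyp1a1 (-4.95 without replicate 1 of second 2i), -2.92 for Ahrr, -0.99 for Nqo1 and -1.1 for Ahr, each of which passed. Of the other targets, Cyp1b1 passed as lower (-3.53), Tiparp passed as higher (0.35) and Aldh3a1 did not pass (0.05).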
